A study of Rattus norvegicus with 12 samples.

How the data were processed

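Per the labels, total RNA of the left kidney was extracted with a column kit and labelled with Cy3 for a single-colour rat array. The labelling kit they name is one for DNA, and the mass of RNA labelled per array is not given in the sources used here. Per the file headers, the arrays were read with Agilent Feature Extraction 9.5.1.1, which subtracts background and removes spatial and multiplicative trends within each array, and the probes were placed on the rat genome build rn4. The processed signal of a spot is an intensity, per the file headers, with no normalization between arrays. The mean spot signal and the median local background are also intensities, per the file headers, without correction. The flags for spots well above background, saturated spots and outlier spots are values of 0 or 1, per the file headers. The authors' value table, as deposited, holds log2 values. A comparison with the scanner values showed that they are relative to the 75th percentile of the array and then to the median of the probe over the 12 arrays.

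The value table covered all 30367 probes, its lowest Pearson correlation across probes with values remade from the scanner files was 0.998, and the largest median of a probe over the arrays was 4.8e-07. The column medians were -0.0011, -0.03, 0.30 and 0.01 for sham replicates 1 to 4, -0.11, -0.16, 0.0020 and -0.21 for day 3 replicates 1 to 4, and 0.01, 0.04, 0.0051 and 0.12 for day 7 replicates 1 to 4. The values are thus centred on the probe, so they carry differences between arrays and no level. They were used here as an alternative to the scanner values.

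Log2 values of the processed signal were taken, and the 75th percentile of each array was subtracted. Spots called non-uniform or population outliers were set aside, and the spots of a probe were averaged (1390 probes had several). This scaling sets the 75th percentile of all arrays equal, although the unscaled percentile was 2.17 times higher at day 3 than in sham, so all changes are relative to it. A probe was kept if it stood well above background on all 4 arrays of at least 1 group, which left 21066 probes. The probe with the highest mean stood for its gene, which left 18507 genes, 12670 of them with a name that is not only an accession. Every tested gene had a value on at least 2 arrays of each group.

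Probe names came from the accession in the files for 18343 probes, from the symbol for 2213 and from a synonym for 596, by a current rat gene table on the assembly GRCr8, used for names only. For 9215 probes the name in the files was kept, and 4596 names were updated. Of 2316 genes with several tested probes, 62 had a probe called in the other direction at day 3, 3 at day 7 and 12 between the days. Probes of gene families with close relatives can bind more than 1 transcript. The text marks this for Ugt2b37, Adh1c and C4a, and other named genes may also belong to such families.

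Genes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 mean per group and a spread shared by all 12 arrays. Tests were two-sided, p values were adjusted by the method of Benjamini and Hochberg over all tested genes, and the threshold was 0.05. The replicate numbers do not pair rats across groups: of 12 pairs of arrays with the same number, 3 matched best with their own number, and the correlations of their deviations from the group mean ran from -0.330 to 0.142. The arrays lay on 3 slides of 4 and were scanned in 2 batches. The mean correlation of deviations was 0.0629 between arrays of a slide and -0.0283 between slides. The slide and the scan batch were each used as a block in alternatives, and comparisons were repeated within each slide.

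The 29 gene lists, with 605 genes of which 595 had a probe, covered parts of the nephron, other cell types, processes of injury and repair, and neighbouring tissues. They were tested with camera of limma at a preset correlation between genes of 0.01, with p values adjusted over the lists. 4 genes stand in more than 1 list. 89 genes without a value on some array were left out of the list tests. Alternatives were camera with an estimated correlation and fry, and 23, 16 and 20 lists passed by fry in the comparisons of day 3 with sham, day 7 with sham and day 7 with day 3. At day 7 against sham these were not the same lists as by camera: fry left out proximal tubule transport and collecting duct and took in MHC class II and adrenal genes. Fry tests whether the genes of a list move at all, not whether they move apart from the other genes. Where many genes change, a pass by fry is thus weak evidence for what camera tests. The median, the mean and the test had the same sign in all lists that passed.

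Where a probe was well above background on no array of a group, a fitted fold change has no meaning as a size. A lower bound was then made by setting each array of that group to its own value or, if higher, to the lowest value of any probe well above background on that array, and it is written as at least that fold. Where only some arrays of a group stood above background, their number is given.

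The genes named were set by a rule. At each time against sham it takes the 8 largest rises and the 8 largest falls among genes past the threshold with groups that do not overlap and with a signal above background on at least 3 of 4 arrays in both groups, and 5 of each between the days. Of each list it takes up to 3 called members with the largest change and up to 1 called member against the majority. It always takes Havcr1, Lcn2, Spp1, Cd44, Vim, Sox9, Pax2, Prom1, Cdkn1a, Col1a1, Mki67 and Cd68, and the 4 genes with the largest lower bound in each direction. Some genes that the rule took are not reported here, and the other 314 results for genes are printed in part. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, apart from 3 alternatives, 3 gene lists and some tests of explanations that were added later. The tests on clock genes, NRF2 genes and the share of proximal tubule cells were chosen after the result was seen. The added alternatives are scaling to the total signal, leaving out sham arrays 2 and 3, and normexp correction without spots below their local background.

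In a self-test, 12 arrays were simulated from the sham mean and the spread of each gene, and 200 genes were changed in each of 20 simulations. A change of 1.5-fold was recovered for 11.4% of genes, 2-fold for 44.8%, 3-fold for 74.6% and 4-fold for 85.1%, and 5.06% of calls were false. A shifted list was found in 100.0% of the simulations, with a mean of 0.05 other lists called. The simulated noise was independent between genes, so the list result does not cover lists whose genes move together. Far fewer genes were changed than passed in the real comparisons, so the recovered shares apply to the simulated setting only. Tables were handled with the R package data.table (version 1.17.8), python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.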

Results

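RNA levels were measured in the whole left kidney of female F344 rats, an inbred strain, at 10 weeks of age. In unilateral ischemia-reperfusion injury (IRI) the blood supply of 1 kidney is stopped for a time and then restored. The groups were sham-operated rats killed at day 7, injured rats at day 3 and injured rats at day 7, with 4 rats and so 4 arrays in each. There was no sham group at day 3, so the comparison of day 3 with sham also spans different times after the operation. The title of the series speaks of adaptive and maladaptive repair of renal tubules. The assay was an Agilent single-colour microarray, on which the brightness of a labelled probe spot follows the amount of an RNA.

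Each array held 42877 spots of 30367 probes other than controls. The 75th percentile of the processed signal was 328 ± 72.6 intensity units (SD, n = 4) in sham, 714 ± 34.5 (SD, n = 4) at day 3 and 502 ± 60.9 (SD, n = 4) at day 7. It was 2.17 times sham at day 3 and 1.53 times sham at day 7, each with a two-sided exact permutation p of 0.0286, the smallest that 4 arrays against 4 can give. The mass of RNA labelled per array is not given in the sources used here, so this unscaled signal is no measure of the RNA in a kidney. The 100 brightest probes carried 29.6% ± 2.64 of the signal in sham, 17.8% ± 0.675 at day 3 and 22.5% ± 0.823 at day 7 (SD, n = 4 each). The share of spots well above background was 65.0% to 76.0% in sham, 73.3% to 80.6% at day 3 and 67.1% to 76.2% at day 7. The number of arrays limits the precision. Values below are log2 signals relative to the 75th percentile of their array, with the SD over 4 arrays for a group and the standard error (SE) of the limma fit for a fold change. Adjusted p values are from limma for genes and from camera, a limma test of whether a gene list moves apart from the other genes, for lists.

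Pairwise Pearson correlations across genes between arrays of a group were 0.942 to 0.967 in sham, 0.967 to 0.984 at day 3 and 0.950 to 0.972 at day 7. The arrays lay on 3 slides scanned in 2 batches, and every slide held all 3 groups.

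**Figure D1:**
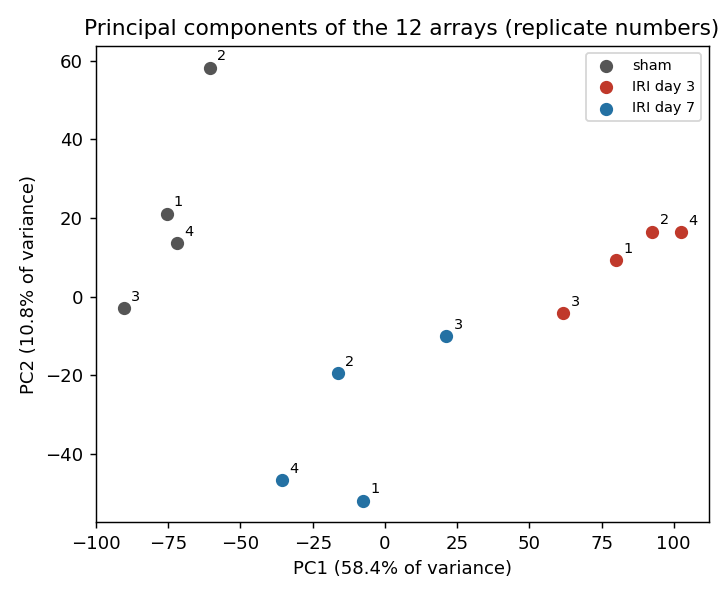
Principal components of the 12 arrays over the tested genes, with the first component (58.4% of the variance) on the horizontal axis and the second (10.8%) on the vertical axis. Points are arrays coloured by group and numbered by replicate, and sham replicate 2 lies apart on the second component at 58.3.

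The first comparison asked which genes differed from sham 3 days after injury. Havcr1, which encodes the injury marker KIM-1, rose 84.9-fold (log2 fold change 6.41 ± 0.59 SE), from -2.34 ± 0.23 (SD, n = 4) in sham to 4.06 ± 0.48 (SD, n = 4). Spp1, which encodes osteopontin, rose 157-fold (7.29 ± 0.37 SE) from a signal above background on 3 of 4 sham arrays. Umod, which encodes uromodulin of the thick ascending limb, fell 56.6-fold, from 5.39 ± 0.16 to -0.43 ± 1.34 (SD, n = 4 each). Pck1, an enzyme of glucose synthesis in the proximal tubule, fell 78.5-fold (-6.29 ± 0.45 SE).

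With limma, 10604 of 18507 tested genes (57.3%) passed an adjusted p of 0.05, 4474 higher and 6130 lower, and 6026 of these differed by at least 2-fold. In 51.7% of all tested genes the arrays of the groups did not overlap, against 2.86% by chance, and 9057 of the called genes were among them. With the slide as a block the count was 10382, with the scan batch 10310, and within the slides 99.4% of the called genes kept their direction on each of the 3. The genes were called on these same arrays, so shares of this kind are largely set by the calling. The share of called genes that were higher was 42.2% with the median gene at -0.13, but 58.5% with the median gene at 0.15 when arrays were scaled to their total signal, a scaling chosen after seeing the data. Normexp background correction lowered the count to 3181 with smaller log2 fold changes for Havcr1 (4.59) and Spp1 (4.52), and ended the calls of Sox9, Cd68, Cx3cr1, Sdha, Atf3, Ccl2, Top2a and Col6a3, all named in this comparison. On 6 arrays up to 25 spots below their local background moved the fitted floor of this correction. Without these spots, a test chosen after seeing the data, it gave 11875 genes. The low counts under normexp here and below thus largely reflect the moved floor.

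Further genes with large rises were the ribonucleotide reductase subunit Rrm2 (45.1-fold, adjusted p = 5.7e-06), Pttg1 of chromosome separation (37.3-fold), the fibrinogen chain gene Fgb (27.4-fold), the chaperone gene Clu (26.7-fold) and the mitotic kinase gene Plk1 (24.2-fold). Rrm2, Pttg1 and Fgb were above background on 3 of 4 sham arrays, and the log2 fold change of Fgb was 4.11 without sham replicate 3, against 4.77. Large falls were seen for Egf, the growth factor of the distal nephron (50.1-fold), Calb1, which encodes the calcium-binding protein calbindin (38.9-fold, above background on 3 of 4 day 3 arrays), and the endonuclease gene Dnase1 (38.3-fold, adjusted p = 3.54e-08). Ugt2b37 fell 87.6-fold and Adh1c fell 38.5-fold, but both belong to multigene families and their probes may bind related transcripts, so their identity is uncertain. In each gene of this paragraph and of the opening, all 4 day 3 arrays lay on the same side of all 4 sham arrays. Il24, a cytokine gene, was at least 30.7-fold higher and the cyclin-dependent kinase subunit gene Cks2 at least 23.4-fold higher, since no sham array stood above background. Rbp4, which encodes the retinol carrier, was at least 63.1-fold lower, since no day 3 array did.

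Injury and repair lists rose. In the tubular injury list 13 of 18 tested genes were higher and 2 lower (median 1.97, adjusted p = 2.07e-06), among them Spp1, Havcr1, Fgb and Clu as higher, and Lcn2, the secreted iron-trapping protein NGAL, rose 4.74-fold. The list had adjusted p = 0.171 with an estimated correlation. In the dedifferentiated or regenerating tubule list 20 of 25 genes were higher and none lower by limma (median 1.30, adjusted p = 2.26e-07), while adjusted p = 0.171 with an estimated correlation. Its members Anxa2, a membrane-binding protein, rose 17.4-fold, Vim, the mesenchymal filament protein vimentin, 9.33-fold, Sox9, a transcription factor of repairing tubules, 5.67-fold (adjusted p = 0.00142) and Prom1, the CD133 gene, 2.76-fold (adjusted p = 0.00199), whereas Pax2 of kidney development stood at 0.27 ± 0.29 SE (adjusted p = 0.438). In the cell cycle list 35 of 37 genes were higher and none lower (median 3.21, or 2.81 with 9 genes at their bounds, adjusted p = 1.6e-18, adjusted p = 0.126 with an estimated correlation). Top2a, the DNA topoisomerase of dividing cells, was at least 11.2-fold higher. Mki67 had no probe by that name.

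Nephron lists fell. In the proximal tubule metabolism list 29 of 30 genes were lower and none higher (median -2.56, adjusted p = 2.73e-09, adjusted p = 0.271 with an estimated correlation), among them the cytochrome gene Cyp2e1 (25.7-fold, or -5.36 and -4.05 in log2 without day 3 replicates 3 and 4, against -4.68). In the proximal tubule transport list 23 of 29 were lower and 2 higher (median -1.88, adjusted p = 1.04e-05, adjusted p = 0.355 with an estimated correlation). The organic anion transporter genes Slc22a6 and Slc22a7 fell 27.6-fold and 28.8-fold, while the glucose transporter gene Slc2a2 rose 4.4-fold. In the thick ascending limb list 10 of 13 were lower and 1 higher (median -2.08, adjusted p = 0.000333, adjusted p = 0.182 with an estimated correlation), with Umod and Egf among the largest falls. In the distal convoluted and connecting tubule list 9 of 10 were lower (median -2.05, adjusted p = 3.48e-05), and this was the list whose call held at an estimated correlation (adjusted p = 0.0414 with an estimated correlation). In the collecting duct list 17 of 18 were lower (median -1.57, adjusted p = 4.12e-06, adjusted p = 0.225 with an estimated correlation), among them the anion exchanger gene Slc4a1 (8.94-fold) and the ammonia transporter gene Rhcg (6.28-fold). The blood and skeletal muscle list also holds Slc4a1, so its fall need not come from the collecting duct.

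In the fatty acid oxidation list 21 of 29 genes were lower and none higher (median -1.03, adjusted p = 1.14e-06, adjusted p = 0.217 with an estimated correlation), with the peroxisomal enzyme gene Ehhadh 16.7-fold and the lipid-sensing receptor gene Ppara 10.1-fold lower. In the mitochondrial respiration list 16 of 30 were lower, such as the succinate dehydrogenase gene Sdha (2.07-fold), with a median of -0.39 that turned to 0.07 under normexp correction (adjusted p = 0.00344, adjusted p = 0.414 with an estimated correlation). The NRF2 and oxidative stress list, a mix of genes under the factor NRF2 and other antioxidant genes, had 11 of 19 lower and 3 higher (median -0.68, adjusted p = 0.0487, adjusted p = 0.355 with an estimated correlation), and its call ended with the slide as a block (adjusted p = 0.0716). Its members Osgin1 and Gclc, the latter an enzyme of glutathione synthesis, fell 10.6-fold and 9.22-fold, while Srxn1, which restores oxidised peroxiredoxins, rose (1.87 ± 0.24 SE). In the glycolysis and hypoxia response list 8 of 24 were higher and 6 lower around a median of -0.04 (adjusted p = 0.652), a sign that turned to 0.24 under total signal scaling. The phosphofructokinase gene Pfkp rose (2.47 ± 0.24 SE) and the vascular growth factor gene Vegfa fell 4.99-fold.

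Matrix and immune lists rose in part. In the fibroblast and extracellular matrix list 26 of 30 genes were higher and 2 lower (median 1.71, adjusted p = 3.25e-09, adjusted p = 0.126 with an estimated correlation), with the fibronectin gene Fn1 9.64-fold and the collagen gene Col1a1 5.47-fold higher. In the macrophage list 15 of 19 were higher and 1 lower (median 1.78, or 1.51 with bounds, adjusted p = 3.08e-06, adjusted p = 0.142 with an estimated correlation), where the lipid receptor gene Trem2 rose 14.1-fold, the lysosomal marker Cd68 6.5-fold (2.70 in log2, and 1.99 without sham replicate 3) and Cx3cr1, a chemokine receptor of resident macrophages, fell 2.42-fold. In the inflammatory cytokines and chemokines list 17 of 21 were higher and 1 lower (median 1.59, adjusted p = 9.1e-07, adjusted p = 0.126 with an estimated correlation), and the chemokine gene Ccl2 was at least 7.88-fold higher. In the complement list 13 of 18 were higher and 2 lower (median 1.31, adjusted p = 0.000277, adjusted p = 0.171 with an estimated correlation), with C3 at 7.11-fold. In the interferon response list 16 of 24 were higher and 2 lower, such as the transcription factor gene Irf1 (6.81-fold), with a median of 1.33 that turned to -0.12 under normexp correction (adjusted p = 0.000141, adjusted p = 0.171 with an estimated correlation). In the immediate early and AP-1 list 14 of 18 were higher and 1 lower (median 1.82, adjusted p = 3.08e-06, adjusted p = 0.171 with an estimated correlation), the stress factor gene Atf3 by at least 12.03-fold.

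In the p53 and cell cycle arrest list 9 of 19 genes were higher and 2 lower (median 0.91, adjusted p = 0.0115, adjusted p = 0.171 with an estimated correlation), such as the antiproliferative gene Btg2 (5.53-fold higher). Cdkn1a, which encodes the cell cycle inhibitor p21, depended on its probe. The brighter probe on chromosome 20 from 7385536 to 7385595 gave 0.08 ± 0.20 SE (adjusted p = 0.757), and the other, from 7386596 to 7386655, gave 4.58 ± 0.39 SE (adjusted p = 7.91e-06). Col6a3, a matrix collagen gene, also had probes that parted, at -0.86 ± 0.23 SE and 1.49 ± 0.35 SE. Less bright probes moved in the same direction but by other sizes for Irf1 (0.99 against 2.77), Col1a1 (4.49 against 2.45), Fn1 (4.20 against 3.27), Vwf (-3.55 and -1.64 against -2.99) and Ugt2b37 (-0.88 against -6.45). The elastin gene Eln stood at 2.43 by its brightest probe (adjusted p = 7.94e-05) and at -0.47 by the other (adjusted p = 0.0101). In the endothelium list 10 of 17 were lower and none higher (median -1.04, adjusted p = 0.00344, adjusted p = 0.35 with an estimated correlation), with the von Willebrand factor gene Vwf 7.94-fold lower. The adrenal list, kept as a sign of neighbouring tissue, had 4 of 6 lower (median -1.07, adjusted p = 0.0285, adjusted p = 0.35 with an estimated correlation). It lost its call without sham replicate 3 (adjusted p = 0.0549).

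The other lists did not pass. The podocyte list had a median of -1.16 (adjusted p = 0.0533), with 7 of 13 genes lower and 2 higher, and the slit diaphragm gene Nphs1 fell 6.41-fold. The medians were -0.50 for 3 tested neutrophil genes (adjusted p = 0.805), 0.17 for T and NK lymphocyte genes (adjusted p = 0.228), 0.81 for B lymphocyte and plasma cell genes (adjusted p = 0.524) and -0.10 for MHC class II antigen presentation (adjusted p = 0.805). They were -0.75 for renal endocrine and vasoactive genes (adjusted p = 0.154), -0.28 for adipose genes (adjusted p = 0.767) and -1.06 for blood and skeletal muscle genes (adjusted p = 0.157). In the endocrine list Kl, which encodes klotho, fell 4.51-fold and the vitamin D receptor gene Vdr 4.62-fold.

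Of the 29 lists, 20 passed, 10 higher and 10 lower, and 1 passed with an estimated correlation. All 20 kept the sign of their median with the slide as a block and within each of the 3 slides. For example, the block gave 3.05 for the cell cycle list and -2.43 for proximal tubule metabolism, and the slides gave 2.84, 3.70 and 3.12 for the former and -1.99, -3.20 and -2.16 for the latter. Adjusted over the list alone, the counts of members were the same as those given, except 8 lower podocyte genes, 16 higher macrophage genes, 22 lower fatty acid oxidation genes, 18 higher cytokine genes, and 3 lower interferon genes.

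**Figure D2:**
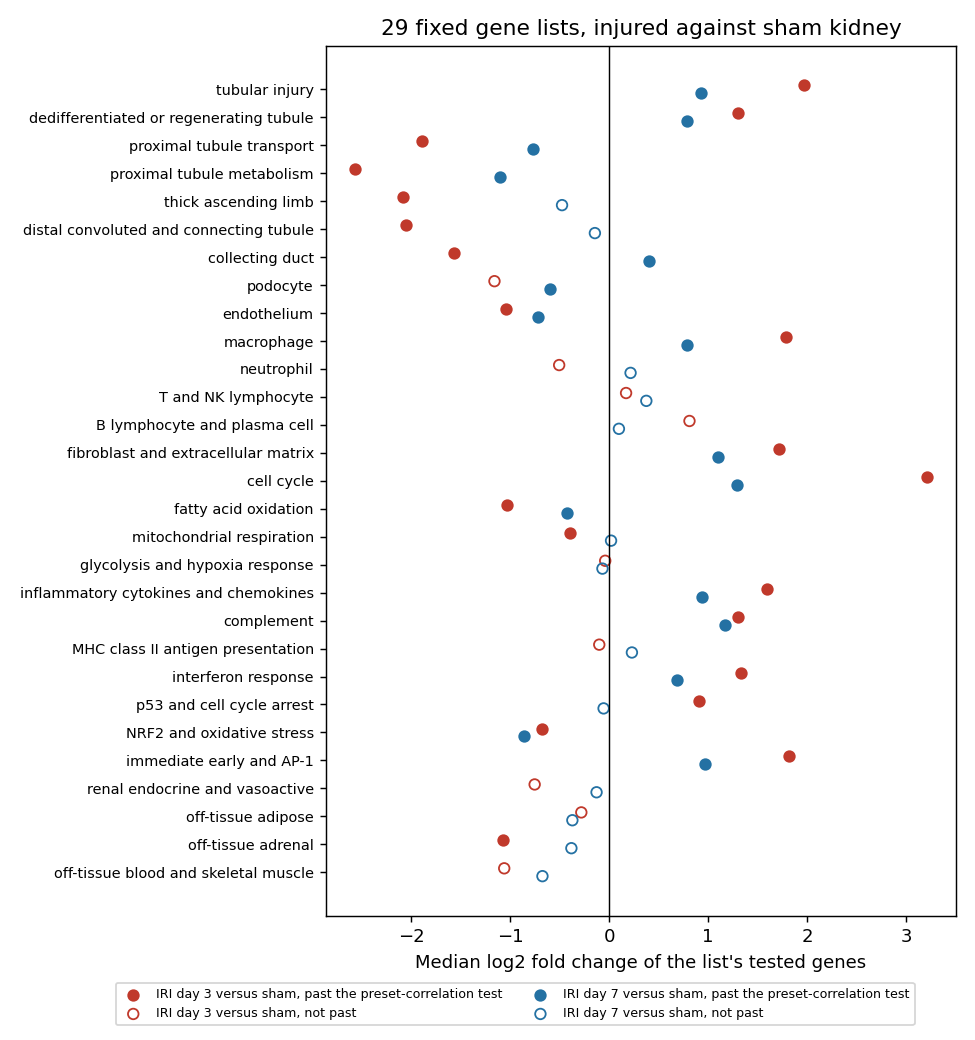
Median log2 fold change (horizontal axis) of the tested genes of each of the 29 lists (vertical axis), at day 3 in red and at day 7 in blue, both against sham. Filled points passed the test with the preset correlation, and the medians of the collecting duct list were -1.57 and 0.40. With an estimated correlation that list did not pass at either time.

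The second comparison asked what still differed from sham 7 days after injury, with both groups at the same time after the operation. Spp1 remained 135-fold above sham (7.08 ± 0.37 SE, adjusted p = 4.26e-06), at 3.56 ± 0.86 against -3.51 ± 0.45 (SD, n = 4 each). C4a, a complement component gene with close relatives, rose 14.03-fold (3.81 ± 0.35 SE), and Clu rose 12.4-fold. The macrophage gene Trem2 rose 10.3-fold and the complement factor D gene Cfd 8.73-fold. The organic anion transporter gene Slc22a7 fell 13.1-fold, Gldc, an enzyme of glycine breakdown, fell 14.1-fold and Pck1 fell 12.4-fold. In all of these the 4 day 7 arrays lay on the same side of the 4 sham arrays.

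With limma, 3492 of 18507 genes (18.9%) passed, 1522 higher and 1970 lower, and 1362 of these differed by at least 2-fold. Arrays of the groups did not overlap in 21.7% of all genes, against 2.86% by chance. The slide block gave 3333 genes and the scan batch block 3216, and 99.7%, 99.6% and 99.9% of the called genes kept their direction within the slides. The share of called genes that were higher was 43.6%, but 55.3% in the authors' value table and 78.0% under total signal scaling, where the median gene moved from -0.07 to 0.17. The count was 91 under normexp correction, where of the called genes named for this comparison Spp1, C4a, Clu, Gldc, Pck1, Mmp2, Col1a1, Slc7a13, Osgin1 and Gclc still passed. Normexp without the spots below their local background gave 3530. The count was 1548 without sham arrays 2 and 3, 2222 without day 7 replicate 1 and 2001 without day 7 replicate 3.

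In the tubular injury list 10 of 18 genes were higher and none lower (median 0.93, adjusted p = 3.11e-08, adjusted p = 0.175 with an estimated correlation). The day 7 rats differed among themselves in this list, with means of 0.96 and 1.04 in replicates 1 and 3, but 0.0034 and -0.23 in replicates 2 and 4, against -1.42 to -1.16 in sham and 1.17 to 1.36 at day 3. Cytokine means parted the same 2 pairs, at -0.58 and -0.31 against -1.12 and -1.43, as did interferon response means, at -0.85 and -0.98 against -1.55 and -1.46. The pairs do not follow the slides. Havcr1 rose 5.8-fold (2.53 ± 0.59 SE, adjusted p = 0.0136) with a wide spread at day 7 (0.19 ± 1.57 SD, n = 4) and 3.24 without day 7 replicate 4, and this call ended without sham arrays 2 and 3 (adjusted p = 0.073). In the dedifferentiated or regenerating tubule list 11 of 25 were higher and none lower (median 0.78, adjusted p = 8.44e-07, adjusted p = 0.18 with an estimated correlation), with Sox9 4.72-fold and Anxa2 4.53-fold higher. Vim stood at 1.07 ± 0.45 SE (adjusted p = 0.115), Prom1 at 0.55 ± 0.31 SE (adjusted p = 0.242) and Pax2 at 0.15 ± 0.29 SE (adjusted p = 0.764). In the cell cycle list 19 of 37 were higher and 1 lower, the cyclin gene Ccnd1 (not past without sham arrays 2 and 3), with a median of 1.29 that was 0.88 with bounds and turned to -0.16 under normexp correction (adjusted p = 6.53e-11, adjusted p = 0.18 with an estimated correlation). Rrm2 rose 6.46-fold (adjusted p = 0.0026; 2.69 in log2, and 1.96 without sham arrays 2 and 3) and Top2a was at least 3.75-fold higher.

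In the fibroblast and extracellular matrix list 17 of 30 were higher and 1 lower (median 1.096, adjusted p = 2.54e-10, adjusted p = 0.126 with an estimated correlation). The elastin gene Eln rose 6.2-fold by its brightest probe and stood at -0.25 by the other (adjusted p = 0.206), the matrix protease gene Mmp2 4.76-fold and Col1a1 3.83-fold (adjusted p = 0.00117; 4.16 against 1.94 in log2 by another probe), while Ccn2, a matrix-inducing growth factor gene, fell 3.83-fold. In the complement list 13 of 18 were higher and 2 lower (median 1.17, adjusted p = 1.48e-08, adjusted p = 0.126 with an estimated correlation). In the macrophage list 9 of 19 were higher and 1 lower (median 0.79, or 0.70 with bounds, adjusted p = 1.79e-06, adjusted p = 0.157 with an estimated correlation), and Cd68 stood at 1.60 ± 0.55 SE (adjusted p = 0.0601). In the inflammatory cytokines and chemokines list 8 of 21 were higher and none lower (median 0.94, adjusted p = 8.53e-06, adjusted p = 0.168 with an estimated correlation), among them the TWEAK receptor gene Tnfrsf12a (4.18-fold). In the interferon response list 7 of 24 were higher, Irf1 by 3.97-fold (another probe stood at 0.36, adjusted p = 0.527), and 1 lower, with a median of 0.68 that turned to -0.08 under normexp correction (adjusted p = 0.00165, adjusted p = 0.308 with an estimated correlation). In the immediate early and AP-1 list 11 of 18 were higher and 1 lower (median 0.97, adjusted p = 1.53e-05, adjusted p = 0.21 with an estimated correlation). Atf3 was at least 3.15-fold higher on the 3 day 7 arrays that measured it.

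In the proximal tubule metabolism list 9 of 30 genes were lower and none higher (median -1.10, adjusted p = 3.4e-07, adjusted p = 0.401 with an estimated correlation), such as the glutathione transferase gene Gsta1 (5.94-fold). In the proximal tubule transport list 11 of 29 were lower and 1 higher (median -0.77, adjusted p = 0.00326, adjusted p = 0.585 with an estimated correlation, not past by fry at adjusted p = 0.0845), such as the amino acid transporter gene Slc7a13 (13.7-fold). In the fatty acid oxidation list 11 of 29 were lower and none higher (median -0.42, adjusted p = 5.95e-06, adjusted p = 0.321 with an estimated correlation), with the peroxisome gene Pex11a 3.91-fold lower. In the NRF2 and oxidative stress list 12 of 19 were lower and 1 higher (median -0.86, adjusted p = 4.29e-06, adjusted p = 0.151 with an estimated correlation). Osgin1 fell 8.68-fold (adjusted p = 7.16e-05) and Gclc 8.25-fold, while Srxn1 rose 2.62-fold. In the podocyte list 4 of 13 were lower and none higher (median -0.60, adjusted p = 0.0239, adjusted p = 0.415 with an estimated correlation), Nphs1 by 3.17-fold. In the endothelium list 5 of 17 were lower and none higher (median -0.72, adjusted p = 0.000515, adjusted p = 0.332 with an estimated correlation), Vwf by 3.01-fold.

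The collecting duct list rose by a median of 0.40 (adjusted p = 0.00356, adjusted p = 0.477 with an estimated correlation, not past by fry at adjusted p = 0.0966), although 2 of its 18 genes passed as higher and 1 as lower. These were Aqp4, a water channel gene (7.02-fold, adjusted p = 0.00725, not past without sham arrays 2 and 3), Hsd11b2, which inactivates glucocorticoids in the collecting duct (2.46-fold, adjusted p = 0.00232), and Slc4a1 (-0.82, not past in the authors' value table). Slc4a1 also stands in the blood and skeletal muscle list. Other Aqp4 probes stood at 2.11 (adjusted p = 0.0259) and 0.82 (adjusted p = 0.0747), against 2.81. The thick ascending limb list had a median of -0.47 (adjusted p = 0.476), with Egf 4.07-fold lower and the potassium channel gene Kcnj1 higher by 0.83 (not past without sham arrays 2 and 3, nor by a probe at 0.48, adjusted p = 0.41). The distal convoluted and connecting tubule list had a median of -0.14, or 0.09 under total signal scaling (adjusted p = 0.716). Mitochondrial respiration stood at 0.02 (adjusted p = 0.716), the p53 list at -0.06 (adjusted p = 0.515), glycolysis and hypoxia at -0.07 (adjusted p = 0.515) and MHC class II at 0.23 (adjusted p = 0.301). Cdkn1a of the p53 list again depended on its probe. The brighter probe, used in the list, stood at -0.20 ± 0.20 SE, and the other at 3.02 ± 0.39 SE (limma adjusted p = 0.000775). The T and NK lymphocyte list stood at 0.38 (adjusted p = 0.108), the B lymphocyte list at 0.10 (adjusted p = 0.408), the neutrophil list at 0.22 (adjusted p = 0.716) and renal endocrine genes at -0.13 (adjusted p = 0.941). Adrenal genes stood at -0.38 (adjusted p = 0.101), adipose genes at -0.37 (adjusted p = 0.515) and blood and muscle genes at -0.67 (adjusted p = 0.347).

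Of the 29 lists, 16 passed, 10 higher and 6 lower, and none passed with an estimated correlation, against 16 at an unadjusted camera p of 0.05 and 16 by fry. The lists by fry differ from those by camera, without proximal tubule transport and collecting duct and with MHC class II (adjusted p = 0.0163) and adrenal genes (adjusted p = 0.044). All 16 by camera kept the sign of their median with the slide as a block and within each slide, for example 0.36 with the block and 0.35, 0.69 and 0.07 within slides for the collecting duct list. Adjusted over the list alone, more members passed in several lists, such as 21 lower proximal tubule metabolism genes, 14 lower and 2 higher proximal tubule transport genes, 25 higher and 2 lower cell cycle genes, 12 higher macrophage genes, 19 higher and 2 lower matrix genes, 13 lower NRF2 genes and 13 lower fatty acid oxidation genes. For tubular injury, collecting duct, complement, podocyte and cytokine genes these counts were the same as those over all genes.

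The third comparison asked how the injured kidney changed between day 3 and day 7. Calb1 rose 116-fold (6.86 ± 0.35 SE, adjusted p = 1.51e-06), from -3.85 ± 0.88 to 3.01 ± 0.18 (SD, n = 4 each), and was above background on 3 of 4 day 3 arrays. Dnase1 rose 22.8-fold and Umod 19.4-fold. Havcr1 fell 14.7-fold (-3.87 ± 0.59 SE, adjusted p = 0.00141; -3.16 without day 7 replicate 4). Il1rl1, the interleukin-33 receptor gene, fell 22.2-fold and Il24 fell 14.4-fold, both above background on 3 of 4 day 7 arrays. Without day 7 replicates 1 and 4 in turn Il24 stood at -4.49 and -3.22, against -3.85. Fam25a fell 23.3-fold (-4.54 in log2, -2.93 by another probe and -3.91 without day 3 replicate 4), and Ppp1r1a, a phosphatase inhibitor gene, rose 15.3-fold.

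With limma, 5816 of 18507 genes (31.4%) passed, 3334 higher and 2482 lower at day 7, and 2356 of these differed by at least 2-fold. Arrays of the groups did not overlap in 36.2% of all genes, against 2.86% by chance. The slide block gave 4915 genes and the scan batch block 5790, and 98.7%, 99.5% and 99.98% of the called genes kept their direction within the slides. The count was 160 under normexp correction, which ended the calls of Il1rl1, Il24, Aqp4, Lcn2, Myc, Sdha, Irf7, Cat, Nr3c2, Tagln, Slc2a2, Cxcl1, Ccl2 and Ttk. Normexp without the spots below their local background gave 7856. The count was 3638 without day 3 replicate 2 and 3448 without day 3 replicate 4.

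Nephron lists rose between the days. All 18 collecting duct genes were higher (median 2.11, adjusted p = 1.28e-13, adjusted p = 0.18 with an estimated correlation), among them Aqp4 (9.23-fold, or 3.21 in log2, with 2.35 and 1.90 by other probes and 2.59 without day 3 replicate 2), the sodium channel subunit gene Scnn1g (8.03-fold) and Rhcg (7.8-fold). In the distal convoluted and connecting tubule list 9 of 10 were higher (median 1.56, adjusted p = 8.01e-08), which held at adjusted p = 0.00611 with an estimated correlation, and the sodium chloride cotransporter gene Slc12a3 rose 5.66-fold. In the thick ascending limb list 9 of 13 were higher (median 1.61, adjusted p = 1.18e-05, adjusted p = 0.194 with an estimated correlation), with Egf 12.3-fold higher. In the proximal tubule metabolism list 25 of 30 were higher (median 1.41, adjusted p = 5.67e-09, adjusted p = 0.328 with an estimated correlation). In the proximal tubule transport list 18 of 29 were higher and 1, Slc2a2, lower (median 1.13, adjusted p = 3.11e-06, adjusted p = 0.358 with an estimated correlation), with Slc22a6 8.56-fold and the phosphate transporter gene Slc34a1 8.33-fold higher. In the fatty acid oxidation list 17 of 29 were higher (median 0.65, adjusted p = 5.06e-05, adjusted p = 0.328 with an estimated correlation), and in the mitochondrial respiration list 14 of 30 (median 0.40, adjusted p = 1.82e-05, adjusted p = 0.328 with an estimated correlation), Sdha by 1.99-fold. None in these 2 lists was lower.

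Cell cycle genes fell, 36 of 37 (median -2.03, adjusted p = 2.44e-21, adjusted p = 0.163 with an estimated correlation), and the mitotic kinase gene Ttk was at least 6.07-fold lower. In the tubular injury list 6 of 18 were lower, among them Lcn2 (2.44-fold) and the stress cytokine gene Gdf15 (4.52-fold), with a median of -0.74 that was -0.69 with the slide block and -1.37, 0.08 and -0.63 within slides (adjusted p = 0.00391, adjusted p = 0.373 with an estimated correlation). In the dedifferentiated or regenerating tubule list 11 of 25 were lower, Vim by 4.45-fold (median -0.41, adjusted p = 0.000188, adjusted p = 0.324 with an estimated correlation). Spp1 (-0.22 ± 0.37 SE, adjusted p = 0.672), Sox9 (-0.26, adjusted p = 0.713), Cd44 (-0.41, adjusted p = 0.224) and Col1a1 (-0.51, adjusted p = 0.161) did not pass, although a less bright Cd44 probe did (-1.64, adjusted p = 0.0449). In the fibroblast and extracellular matrix list 8 of 30 were lower, such as the contractile protein gene Tagln (4.78-fold; median -0.61, adjusted p = 0.000188, adjusted p = 0.297 with an estimated correlation). In the inflammatory cytokines and chemokines list 10 of 21 were lower (median -0.71, adjusted p = 5.06e-05, adjusted p = 0.194 with an estimated correlation), such as Cxcl1 (19-fold, or -4.90 against -4.25 in log2 without day 7 replicate 3) and Ccl2 (12.5-fold), each above background on 2 of 4 day 7 arrays. In the macrophage list 6 of 19 were lower and 1 higher (median -0.55, adjusted p = 0.00113, adjusted p = 0.297 with an estimated correlation).

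In the immediate early and AP-1 list 6 of 18 genes were lower and 1 higher (median -0.85, adjusted p = 0.000136, adjusted p = 0.297 with an estimated correlation), with the growth regulator gene Myc 3.06-fold lower. In the interferon response list 6 of 24 were lower and 2 higher (median -0.78, adjusted p = 0.00289, adjusted p = 0.325 with an estimated correlation), with Irf7, a factor that drives interferon genes, 2.86-fold lower. In the p53 list 7 of 19 were lower and 1 higher (median -0.78, adjusted p = 0.00313, adjusted p = 0.194 with an estimated correlation). Its member Cdkn1a stood at -0.28 ± 0.20 SE by its brighter probe and at -1.56 ± 0.39 SE by the other (limma adjusted p = 0.0131). In the renal endocrine list 4 of 15 were higher and 1 lower (median 0.62, adjusted p = 0.0273, adjusted p = 0.358 with an estimated correlation), Vdr by 4.2-fold and the mineralocorticoid receptor gene Nr3c2 by 3.19-fold. That call ended without day 3 replicate 1 (adjusted p = 0.0652) and without day 7 replicate 3 (adjusted p = 0.13). Adrenal genes were higher in 4 of 6 (median 0.68, adjusted p = 0.0264, adjusted p = 0.358 with an estimated correlation).

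The remaining lists did not pass. Complement stood at -0.01 (adjusted p = 0.802), with C4a 3.29-fold higher at day 7 (adjusted p = 0.0048), and NRF2 and oxidative stress stood at -0.18 (adjusted p = 0.195), with the catalase gene Cat 2.67-fold higher. The podocyte list stood at 0.19 (adjusted p = 0.458), endothelium at 0.27 (adjusted p = 0.209), glycolysis and hypoxia at -0.02 (adjusted p = 1) and MHC class II at 0.12 (adjusted p = 0.508). The T and NK lymphocyte list stood at -0.03 (adjusted p = 0.853), the B lymphocyte list at 0.14 (adjusted p = 1) and the neutrophil list at 0.84 (adjusted p = 0.648). Adipose genes stood at 0.00 (adjusted p = 1) and blood and muscle genes at 0.32 (adjusted p = 0.211).

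Of the 29 lists, 18 passed, 9 higher and 9 lower, and 1 passed with an estimated correlation. All 18 kept the sign of their median with the slide as a block, and 17 kept it within each slide, the exception being tubular injury. Adjusted over the list alone, the counts were the same for collecting duct, distal convoluted, cell cycle, fatty acid oxidation, matrix and regenerating tubule genes. They were 23 higher proximal tubule transport genes, 27 higher proximal tubule metabolism genes, 10 higher thick ascending limb genes, 11 lower cytokine genes and 10 lower immediate early genes.

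**Figure D3:**
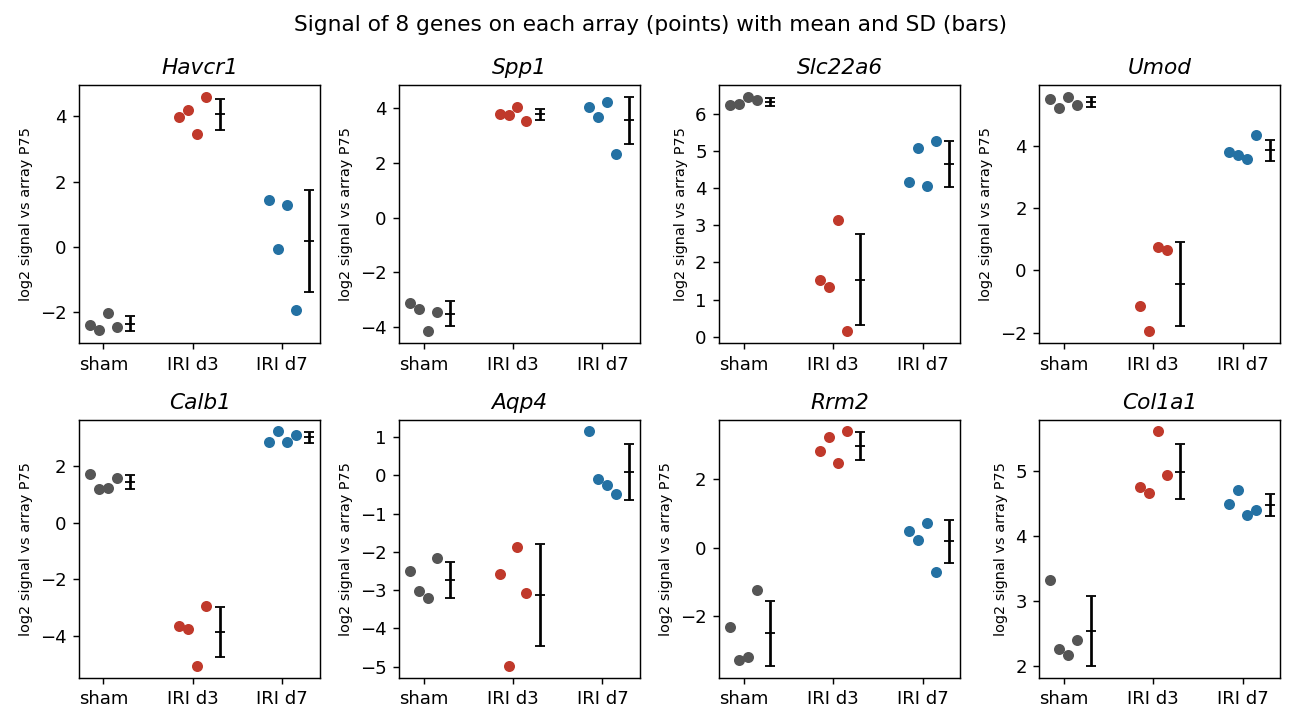
Signal of 8 genes on each array, as log2 relative to the array's 75th percentile (vertical axis), by group (horizontal axis), with points for arrays and bars for the mean and SD of 4 arrays. Calb1 lies at 1.43 in sham, -3.85 at day 3 and 3.01 at day 7, while Spp1 lies at -3.51, 3.78 and 3.56.

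The fourth question was how the differences at the 2 times related. Of the 3492 genes that differed at day 7, 3133 (89.7%) had differed in the same direction at day 3, 1365 of them higher and 1768 lower, against 1020 if the calls were independent. Both comparisons share the sham arrays, and with sham arrays 1 to 4 split so that each comparison used its own pair the count was 1073 to 2457, with at most 674 by independence. Of the 10604 genes that differed at day 3, 5182 (48.9%) moved back towards sham by day 7 by limma, 2121 of them from above and 3061 from below. Of these 5182, 1336 still differed from sham in the same direction at day 7. Moving back or further is judged with the same day 3 arrays as the day 3 call, so chance favours moving back. In simulations without any return, with shared arrays and noise drawn independently for each gene, at most 2 genes were counted as moving back. Such noise leaves out variation that the genes of a rat share, so it may understate what chance can give. The genes alike at both times numbered 85 under normexp correction, 1388 without sham arrays 2 and 3, 2015 without day 7 replicate 1 and 1761 without day 7 replicate 3. Those moving back numbered 142 under normexp correction, 3299 without day 3 replicate 2 and 3121 without day 3 replicate 4. Both normexp counts rest on the fitted floor that a few spots moved, and 7199 genes moved back by normexp without those spots.

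Only 22 genes that differed at day 3 moved further from sham by day 7, 9 upwards and 13 downwards, a number that ran from 10 to 30 when single arrays were left out, at 11 without day 3 replicate 1, 11 without day 3 replicate 2 and 10 without day 3 replicate 4. It was 2 under normexp correction, where a few spots moved the fitted floor, 13 without the filter on dim probes and 48 with array weights. Sharing the day 3 arrays also works against finding genes that moved further. Upwards were C4a (2.09 at day 3, 3.81 at day 7), C6, which encodes a complement component that forms pores (1.27, then 2.46), the secreted glycoprotein gene Scube3 (1.26, then 2.51) and the epithelial gene Fam83e (1.44, then 2.67). Downwards were Ahcy, an enzyme of methionine metabolism (-0.49, then -1.32), the peroxide-removing enzyme gene Prdx6 (-0.50, then -1.10) and the metallothionein gene Mt2A (-0.90, then -1.43). Of these only C4a belongs to the rule for named genes; the others were chosen after their values were seen.

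Only 25 genes passed in opposite directions against sham, 21 of them lower at day 3 and higher at day 7. They included Calb1 (-5.28, then 1.58), Hsd11b2 (-1.31, then 1.30), the potassium channel gene Kcnj1 (-1.85, then 0.83), the epithelial defensin gene Defb1 (-2.10, then 0.86) and Ndrg2 (-1.69, then 0.58). The day 7 call of Calb1 ended without sham arrays 2 and 3 (adjusted p = 0.09). The 4 genes higher at day 3 and lower at day 7 were Akr1b8, an aldehyde-reducing enzyme (0.60, then -1.27), the fatty acid carrier gene Fabp5 (0.98, then -1.26), the Fc receptor gene Fcgr3a (1.05, then -0.96) and Nkain1 (0.63, then -0.74). Defb1, Ndrg2 and these 4 genes were chosen after their values were seen.

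Probe positions are given in the files for the rat genome build rn4. The probe of Havcr1 (A_44_P252517) lies on chromosome 10 from 31857202 to 31857261, and that of Spp1 (A_44_P491796) on chromosome 14 from 6422382 to 6422441. The probe of Umod (A_64_P022545) lies on chromosome 1 from 177729224 to 177729283, and that of Calb1 (A_44_P236255) on chromosome 5 from 30475783 to 30475991. The probe of Pck1 (A_44_P517258) lies on chromosome 3 from 164017597 to 164017656, and that of C4a (A_64_P026316) on chromosome 20 from 4315816 to 4315875. Exons and untranslated regions were not assigned.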

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

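The tests of other splits of the arrays and of medulla genes were set before their result was seen, and the test of a lower share of proximal tubule cells was chosen only after the result was seen. Day 3 and day 7 were compared directly with limma, and 5816 genes differed between them. When the 8 arrays of 2 groups were split in all other ways into 4 and 4, at most 0 genes passed by limma for day 3 with sham (real count 10604), 2 for day 7 with sham (3492) and 0 for day 7 with day 3. In each comparison 1 of 35 splits, the real one, gave as many genes, the smallest share that 4 arrays against 4 can give. Every other split mixed the groups, which widens the spread within them and leaves few calls. These splits alone therefore do not exclude chance. For the counts of lists, other splits reached 21 against 20 for day 3 (4 of 35 splits), 19 against 16 for day 7 (2 of 35) and 19 against 18 between the days (3 of 35), so chance cannot be excluded by this count. The splits that reached as many all kept 3 of the 4 arrays of each group together, and so carry much of the difference between the groups. The 18 splits that mixed the groups evenly reached at most 6, 11 and 14 lists. For the genes that changed the same way at both times (3133), moved back (5182) or moved further (22), 1 of 100 splits of the 12 arrays each, the real one, gave as many, and the highest others were 1, 0 and 0. These counts need genes called against sham, and mixed splits call almost none. They therefore do not test whether, given the changes at day 3, such numbers could arise by chance.

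The collecting duct list lay below sham at day 3 (median -1.57) and above it at day 7 (0.40), and the test of the difference between the days gave a camera adjusted p = 1.28e-13 (adjusted p = 0.18 with an estimated correlation). The day 7 rise against sham was not past the threshold by fry (adjusted p = 0.0966). A lower share of proximal tubule cells at day 7 would raise the markers of all other cell types alike, unless those cells changed as well. Podocyte and endothelium markers had a mean of -0.67 ± 0.55 against sham (SD, n = 30 genes), while collecting duct genes had 0.49 ± 0.74 (SD, n = 18), a difference with a permutation p of 1e-05, the smallest these permutations can give. The rise was thus not shared by these cell types. Their medians were already -1.16 and -1.04 at day 3, so a fall of their own may hide such a rise, and the test cannot decide on that share. Thick limb and distal markers, meant for the same comparison, were left out of the test and had day 7 medians of -0.47 and -0.14. More medulla in the day 7 samples may also raise collecting duct genes, and 7 tested genes of a 10-gene medulla list, 1 of which another list holds, had a median of 0.028 at day 7, against a permutation p of 0.336 for random genes and an exact permutation p of 0.124 against the collecting duct list, so this explanation stays open, as does a change within the injured kidney itself. Genes are not independent replicates, so these p values describe the lists and not the rats.

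Direct tests against sham called 25 genes in opposite directions at the 2 times, and 21 of these, among them Calb1 and Hsd11b2, were lower at day 3 and higher at day 7.

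Single arrays far from the other 3 of their group were sought with a gap, as a share of the group's range, above the 95% critical value of Dixon's test, which chance exceeds in about 5% of groups. This happened in 26 of 573 gene tests, 4 of 87 list tests and 1 of 15 tests of array measures, close to that share for genes and lists. The measure was the number of population outlier spots at day 7, 364 on replicate 1 against 429 to 437 (gap 0.890). The mean of the proximal tubule transport list was 2.46 in sham replicate 3 against 2.67 to 2.69 (0.912). At day 3 the macrophage list mean was 0.91 in replicate 2 against 1.21 to 1.26 (0.871), and the interferon response list mean was -0.81 in the same array against -0.47 to -0.44 (0.927). The blood and skeletal muscle list mean was -1.29 in day 3 replicate 1 against -1.18 to -1.17 (0.871).

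Among genes in sham, Cd68 was at -5.22 in replicate 3 against -2.47 to -2.30 (gap 0.941), and the same array stood apart for Aurka (0.847), Gclc (0.929), Gpnmb (0.858), Kirrel1 (0.881), Ndufv1 (0.887) and Ttk (0.831). Sham replicate 1 stood apart for Pex11a (0.831) and Pfkp (0.842), replicate 2 for Cdkn1c (0.889) and replicate 4 for Ccnd1 (0.855). At day 3, replicate 3 stood apart for Acot12 (0.881), Bbc3 (0.949), Bcl3 (0.878), Kirrel1 (0.909) and Pex11a (0.847), replicate 4 for Birc3 (0.902), Lcn2 (0.832) and Pnpla2 (0.8802), and replicate 2 for Msr1 (0.835) and Nr3c2 (0.928). At day 7, replicate 4 stood apart for Magi2 (0.871) and Nphs1 (0.863), replicate 2 for Irf7 (0.892) and Rhcg (0.943), and replicate 3 for Th (0.861).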

How the results depend on the processing

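Scaling to total signal, leaving out sham arrays 2 and 3, and normexp without spots below their local background were tests chosen only after the data were seen. Of 8682 values of the named genes under alternatives 8117 kept direction and side of the threshold, 525 lost the call, 18 gained one and 22 turned, and of 2433 list values 2386 kept both. Counts over all alternatives ran from 3181 to 13442 genes at day 3, 91 to 4151 at day 7 and 160 to 7876 between the days. Planned normexp correction gave 3181, 91 and 160 genes, 85 genes alike at both times, 142 that moved back and 2 that moved further. On 6 arrays up to 25 spots below their local background moved its fitted floor, which was 57.3 to 957 intensity units with these spots and 57.3 to 64.8 without them. Without them the counts were 11875, 3530 and 7856, with 3197 alike, 7199 back and 26 further. Planned normexp turned at day 3 Ptger3 (-0.43), Cd247 (-0.39), Cd3g (-0.30), Cd22 (-0.65), Fos (-0.045), Edn1 (-0.57) and the mitochondrial respiration median (0.073), at day 7 Bub1 (-0.14), Cxcl10 (-0.024), Egr2 (-0.17), Fos (-0.27) and Edn1 (-0.24), and between the days Msr1 (0.18), Cd55 (0.28) and Nqo1 (0.14). It also turned the medians of the interferon response list at day 3 (-0.12) and day 7 (-0.076) and of the cell cycle list at day 7 (-0.16). Normexp without those spots turned at day 3 Ptger3 (-0.0034), Cd22 (-0.15) and Edn1 (-0.056). Among results for named genes, 14 turned with those spots and 3 without them, so most of these turns rest on the moved floor. Dim signals can limit such values, and why the remaining 3 turned was not tested. The mean of all probes turned Col6a3 at day 3 (0.32) and Cdkn1a at day 7 (1.41), since their probes differ. Cd55 between the days turned to 0.065 without the filter on dim probes and without sham arrays 2 and 3, and with single arrays left out ran from -1.99 to 0.065; the cause was not tested. A 2-fold minimum gave 6026, 1362 and 2356 genes by construction. Camera with an estimated correlation left 1, 0 and 1 lists, against 21, 16 and 18 at an unadjusted p with the preset one and 23, 16 and 20 by fry. Further genes numbered 13 without the filter and 48 with array weights, and day 7 genes numbered 2092 from 8 arrays alone; the causes were not tested. Without sham arrays 2 and 3, 1548 genes passed at day 7 and 1388 were alike. Sham splits, with fewer arrays, gave 1508, 1209, 1868, 1073, 2457 and 1487 genes alike. With replicate number as a block, although the numbers do not pair the rats, 10135, 2468 and 4694 genes passed. Single arrays left out in turn gave 9297 to 10746, 2001 to 3485 and 3448 to 6702 genes, 1761 to 3144 alike, 3121 to 5604 back and 10 to 30 further, and 19 to 21, 15 to 17 and 17 to 18 lists. The day 7 count was 2222 without day 7 replicate 1 and 2001 without replicate 3 (2015 and 1761 alike). The count between the days was 3638 without day 3 replicate 2 and 3448 without replicate 4 (3299 and 3121 back, 11 and 10 further), and 11 went further without day 3 replicate 1.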

Other observations

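The lists of clock genes and the tests of clock and NRF2 genes below were chosen only after the result was seen, and the list of medulla genes was added after the data were seen, before its own values were. Genes driven by the circadian clock were lower after injury. Of 12 listed clock output genes 10 were tested, and 10 were lower at day 3 (median -2.40, limma camera adjusted p = 2.43e-05 over the 3 added lists, and adjusted p = 0.0358 with an estimated correlation) and 8 at day 7 (median -1.26, adjusted p = 5.45e-07, and adjusted p = 0.0154 with an estimated correlation). The transcription factor genes Dbp (-2.39 at day 3, -1.43 at day 7), Tef (-2.41, -1.80) and Hlf (-4.33, -2.93), the protease gene Usp2 (-4.40, -2.37) and Ciart (-4.27, -4.08) are known to follow the clock. Between the days the median rose by 0.79, with 5 genes higher (limma camera adjusted p = 0.0099, and adjusted p = 0.206 with an estimated correlation). Per2 and Bhlhe41 were not tested, and none of the clock genes stands in another list.

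Medulla genes had medians of -0.50 at day 3 (limma camera adjusted p = 0.71), 0.028 at day 7 (adjusted p = 0.562) and -0.16 between the days (adjusted p = 0.945), and 2 of 7 passed as higher and 4 as lower at day 3. The 4 tested genes of the opposite phase of the clock had medians of -0.25 at day 3 (limma camera adjusted p = 0.71), 0.16 at day 7 (adjusted p = 0.465) and -0.13 between the days (adjusted p = 0.951).

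A difference in the time of day of collection may lower clock output genes, and it would then raise genes of the opposite phase. These had a median of -0.25 at day 3 and went both ways, with Nfil3 at 1.76 and Cry1 at -1.88, and Bmal1 was not tested, so time of day and injury cannot be told apart here. Loss of tubule cells may also lower clock output genes. Thick limb, distal and collecting duct genes rose by a mean of 2.004 between day 3 and day 7, against 0.90 for the clock output genes (permutation p = 0.0125). The proximal tubule metabolism list rose by a mean of 1.63 (permutation p = 0.0413 against 0.90). These tests compared log2 changes, not the share of the fall regained. Nr1d2 (-0.86), Nr1d1 (-1.20), Per3 (-1.45) and Cry2 (-1.49) fell at day 3 by less than either mean. Even their full return could not match it, so the tests cannot decide on loss of these cells. Both permutations exchanged genes, which are not independent replicates, so these p values describe the lists and not the rats.

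Of the genes of the NRF2 and oxidative stress list, 11 were lower at day 3, and by day 7 they had regained a mean share of 0.0688 ± 0.323 of that log2 fall (SD, n = 11 genes). The 29 proximal tubule metabolism genes lower at day 3 had regained 0.584 ± 0.167 (SD, n = 29 genes), a difference with a permutation p of 1e-05, the smallest these permutations can give. The members differed, from Mt2A (-0.90 at day 3, -1.43 at day 7), Gsr (-0.68, -0.86) and Me1 (-1.64, -2.04), which stood lower at day 7, to Cat (-2.70, -1.28), with Gclc (-3.21, -3.04) and Osgin1 (-3.41, -3.12) in between. For these 11 genes as a set, this argues against a loss of proximal tubule cells that returned as the metabolism genes did. That list was the only yardstick, and proximal tubule cells need not all return alike. A lasting loss of some of them, and a lower level in the remaining tubule cells, stay open and were not tested. Nqo1 (-0.08 at day 3, -1.46 at day 7) and Gclm (-0.43, -2.90) passed as lower at day 7 and not at day 3, and the test does not cover them. Its permutations also exchanged genes, which are not independent replicates, so its p value describes the lists and not the rats.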
